A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

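The deposited files hold 20 Agilent 2-colour arrays, 4 per slide on 5 slides, with 45209 spots each, of which 43792 are not controls and carry 6256 probes for 6228 genes at 7 spots per probe. Per the labels, cells went from YPD through YPA to sporulation medium, RNA was taken with a Ribopure yeast kit, and it was labelled with the Agilent Quick Amp kit. Per the file headers, the scans were read with Feature Extraction 9.5.3.1, which gives the median intensity of each spot and its local background in scanner units for Cy3 and Cy5, a processed intensity after background subtraction, detrending and dye normalization, and a log10 ratio of Cy5 over Cy3. The authors deposited log2 ratios of Cy3 over Cy5 with a column for each array, with column medians from -0.07 to 0.03. Their exact normalization is not stated, and the columns correlated across genes with the values computed here at r from 0.969 to 1.00, genes not being independent replicates.

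Ratios were computed again from the median intensities in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package in version 1.17.8. Background was corrected with normexp and an offset of 50, and each array was normalized by loess, with controls and spots marked as outliers at weight 0. The log2 ratio of Cy3 (time point) over Cy5 (reference) was averaged over the spots of a probe and the probes of a gene. All arrays have the time point in Cy3 and none has the dyes exchanged. A probe was kept if at least 4 of its 7 spots were well above background in either channel on at least 3 arrays, which removed 92 probes and left 6136 genes. Of the genes on the array 5740 matched a locus tag of the R64 annotation and 488 did not, and of the tested genes 445 did not.

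A limma model with 1 mean per window gave moderated tests for 5 windows against arrest and 3 pairs of consecutive windows, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Change over the whole course was tested with a natural spline of 4 degrees of freedom in which times before release count as 0 min, and the slope before release with a line through the 4 arrest arrays. A midpoint was set between the arrest mean and the peak of a running mean over 3 times. The midpoint time was the first at which the ratio, interpolated between single arrays without smoothing, passed this midpoint. It was read for genes that passed the spline test and whose peak lay at least 1 log2 above the arrest mean. The 23 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Over the 5 windows fry called 45 lists, some of which camera did not call, and missed some that camera called. All list p-values were adjusted together over 23 lists in 5 windows. Genes were named by a rule fixed before the data were examined, with 4 parts. These were NDT80, IME1, IME2, SUM1 and all division regulators and GAL genes, the 8 largest rises and 8 largest falls per window against arrest, the 5 largest per direction between consecutive windows, and up to 4 members of each list with the largest absolute change. The largest rises and falls were taken among genes past the threshold for which every array of the window lay on the same side of every array of the other. The report prints a part of this set, chosen for each list after the values were seen.

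The alternatives were the processed intensities, median centring, the authors' table, no filter and a stricter filter (every array, both channels), quantile scaling of intensities between arrays, the brightest probe of a gene, other spline degrees of freedom, times before release as labelled, a variance trend with robust moderation, only the arrays of both windows, slide as a random and as a fixed block, an estimated correlation, and each array left out in turn. Those added after the data were examined were the Cy3 signal as a covariate, leaving out the 4 arrays with the fewest Cy3 spots above background, the 120 min array or the 3 arrays with a spike-in slope under 0.5, an offset of 10, only annotated genes, and only genes in the upper part by Cy5 signal. Each slide had its own scan, so slide stands for both. Tested on simulated data with the observed spread and 6136 genes, the window model recovered 24% to 45% of changes of 1 log2 and 91% to 95% of changes of 3 log2, with 1 to 11 false calls. The simulated noise was independent between genes and arrays, so effects shared by an array or a slide were not simulated. The spline recovered 98.5% with 16 false calls, and a simulated midpoint of 60 min came out at a median of 61.3 min. The slope test recovered 0% with the spread of whole windows, and 85.5% with 4 false calls with the spread of the arrest arrays. Its simulated slopes were steeper than the list medians reported below. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3. Motif searches were left out because no genome sequence was at hand, and HED1 of the axis list and SAE3 of the recombination list because no probe matched them. NOP56 and SIK1 in the ribosome biogenesis list are names of the same gene, which was counted once.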

Results

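RNA was measured through a synchronised meiosis of budding yeast (Saccharomyces cerevisiae) strain A14201 with 20 Agilent 2-colour arrays, 1 for each labelled time. Ndt80 is the transcription factor that takes meiotic cells out of late prophase I into the divisions and spore formation. Cells were held in the Ndt80 block for 6 hours in sporulation medium, and 1 µM beta-estradiol was then added to induce NDT80. The times ran from 15 min before to 240 min after this release. Each array carried the RNA of 1 time in Cy3 and, in Cy5, RNA of the same strain held in the block. The arrays fell into 6 windows of consecutive times, namely arrest (-15, -10, -5 and 0 min, n = 4), 2 to 15 min (n = 4), and 20 to 60, 80 to 120, 140 to 180 and 200 to 240 min (n = 3 each). A change is the mean log2 ratio of Cy3 over Cy5 of a window minus that of the arrest arrays, or of the window before where consecutive windows are compared, so that a dye effect common to all arrays cancels, and its error is the SE of the fit. The median Cy3 signal of the spots ran from 60.5 scanner units at 120 min to 3400 at 15 min, and that of Cy5 from 5338 to 10377. In Cy3, 68.9% of spots were well above background at 120 min, 84.2% at 20 min, 86.5% at 240 min and 87.9% at 180 min, and at least 92.8% on each of the other 16 arrays. All sample titles name the same time course, and no label says that the samples of a window came from separate cultures. The p-values thus measure the spread between consecutive samples, which includes change over time, and the number of arrays limits the precision. Adjusted p-values for genes are those of limma over 6136 genes, and gene lists were fixed before the data were examined.

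**Figure D1:**
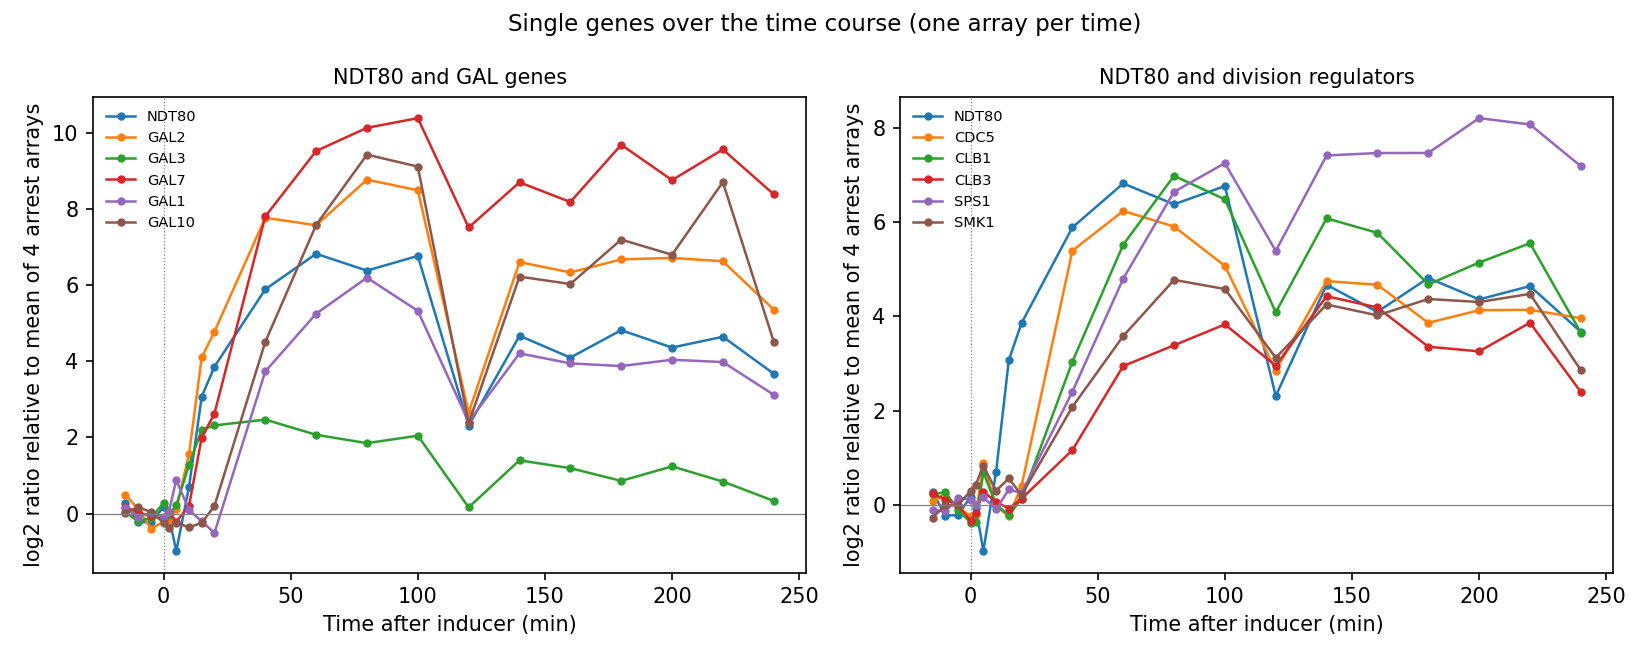
Log2 ratio of single genes relative to the mean of the 4 arrest arrays (y axis) against minutes after the inducer (x axis), 1 array per time, with NDT80 and the GAL genes on the left and NDT80 with division regulators on the right. NDT80 stood at 3.07 at 15 min and 6.82 at 60 min, and CDC5 at 0.40 at 20 min and 5.40 at 40 min.

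The 2 to 15 min window asks what changed in the minutes after the inducer. No single gene passed the limma test in this window, with 552 of 6136 genes at an unadjusted p under 0.05. Within the window NDT80 (YHR124W) stood at 0.70 at 10 min and 3.07 at 15 min relative to arrest, against a window mean of 0.68 ± 0.89 (adjusted p = 0.979). Ribosome biogenesis factors shifted upwards as a list, with a median log2 change of 0.53 over 39 genes (camera adjusted p = 8.74e-05, and adjusted p = 0.72 with an estimated correlation), led by the nucleolar protein NSR1 at 1.88 ± 0.89 and the rRNA methyltransferase NOP1 at 1.33 ± 0.54. Cytosolic ribosomal proteins shifted the same way, with a median of 0.29 over 137 genes (camera adjusted p = 9.61e-05, and adjusted p = 0.723 with an estimated correlation), and 41 of these genes had an upward slope before release. The heat shock and general stress list shifted downwards, with a median of -0.28 over 16 genes (camera adjusted p = 0.00174, and adjusted p = 0.503 with an estimated correlation), and so did the autophagy list at -0.18 over 19 genes (camera adjusted p = 0.0122, and adjusted p = 0.503 with an estimated correlation). In none of these 4 lists did a member pass over all genes, and 0 passed when adjusted over the list alone. With fry the adjusted p was 0.39 for ribosome biogenesis, 0.357 for ribosomal proteins, 0.222 for heat shock and 0.138 for autophagy. The GAL list stood at a median of 0.48 (camera adjusted p = 0.176) and the meiotic division regulators at 0.06 (camera adjusted p = 0.947). The 445 tested genes whose names are not in the annotation table had a median change of 1.74, against 0.00 for the 5691 annotated genes, and the Cy3 signal of these arrays ran from 267 to 3400. All arrest arrays lay on slide 1 and all arrays of this window on slide 2, so slide and time cannot be told apart, and 304 genes passed when the 15 min array was left out.

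Between 20 and 60 min NDT80 itself rose by a log2 change of 5.52 ± 0.96 (adjusted p = 0.00588), and 570 genes changed (limma), 383 upwards and 187 downwards, of which 361 rose and 97 fell at least 2-fold. The largest rises included GAL2 (YLR081W), the galactose permease, at 6.71 ± 1.21 (adjusted p = 0.00588), and GAL7 (YBR018C), a galactose-utilisation transferase, at 6.65 ± 1.11 (adjusted p = 0.00588). Estradiol-inducible strains commonly drive the induced gene through a Gal4 fusion to the estrogen receptor, which also acts on native GAL genes, although the labels do not describe the construct in A14201. Of 10 GAL-list genes 4 rose and 0 fell (adjusted over the list alone, 7 and 0). The GAL list median was 2.07 (camera adjusted p = 5.26e-05, and adjusted p = 0.503 with an estimated correlation). Among 12 meiotic division regulators 3 rose and 0 fell (adjusted over the list alone, 8 and 0), namely the polo kinase gene CDC5 (YMR001C) at 4.01 ± 0.95 (adjusted p = 0.0194) and the spore-formation kinase genes SPS1 (YDR523C) at 2.48 ± 0.68 (adjusted p = 0.0323) and SMK1 (YPR054W) at 1.96 ± 0.58 (adjusted p = 0.0443). This list had a median of 1.95 (camera adjusted p = 0.000126, and adjusted p = 0.514 with an estimated correlation), and its B-type cyclin CLB1 stood at 2.90 ± 0.90 (adjusted p = 0.0519).

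Of 20 genes for the prospore membrane and the meiotic spindle pole plaque, 3 rose and 0 fell (adjusted over the list alone, 11 and 1), including ADY4 at 3.31 ± 0.95 and SPO74 at 3.01 ± 0.87. These means span a range within the window, SPO74 standing at -0.035 at 20 min, 3.76 at 40 min and 5.31 at 60 min, and CDC5 at 0.40 at 20 min, 5.40 at 40 min and 6.24 at 60 min. The prospore membrane median was 2.04 (camera adjusted p = 5.79e-05, and adjusted p = 0.544 with an estimated correlation). In the spore wall list 2 rose and 0 fell (adjusted over the list alone, 8 and 0) among 20 genes, with OSW2 at 2.88 ± 0.86 and well above background on 2 of the 3 arrays. The spore wall median was 1.46 (camera adjusted p = 0.00418, and adjusted p = 0.578 with an estimated correlation). The monopolin gene MAM1 rose by 2.63 ± 0.65 and the casein kinase gene HRR25 by 2.39 ± 0.43, the 2 members that rose among 9 in the meiosis I segregation list (camera adjusted p = 0.883). Cytosolic ribosomal proteins were the list with the most members called at this time: of 137, 63 rose and 0 fell (adjusted over the list alone, 96 and 0). The ribosomal protein median was 1.14 (camera adjusted p = 7.52e-28, and adjusted p = 0.503 with an estimated correlation). RPP1A rose by 2.21 ± 0.50 and RPS15 by 2.15 ± 0.37. Without the 3 arrays of low spike-in slope (5, 40 and 120 min) 17 ribosomal protein genes rose. In that list 41 genes also had an upward slope over the 4 arrays before release. Ribosome biogenesis genes had a median of 0.62 with 3 of 39 risen (camera adjusted p = 0.00378, and adjusted p = 0.824 with an estimated correlation). It was -0.06 without the 4 dim arrays (20, 120, 180 and 240 min), which had the fewest Cy3 spots above background. Of 29 amino acid biosynthesis genes, 4 rose and 0 fell (adjusted over the list alone, 5 and 0), with the methionine synthase gene MET6 at 1.75 ± 0.32. The amino acid median was 0.60 (camera adjusted p = 0.00904, and adjusted p = 0.514 with an estimated correlation). After median centring the camera adjusted p was 0.0525 for the spore wall and 0.169 for amino acid biosynthesis, and without the 4 dim arrays it was 0.0957 for amino acid biosynthesis and 0.136 for heat shock, and ribosome biogenesis did not pass either.

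On the falling side at 20 to 60 min stood the alcohol dehydrogenase gene ADH2 (YMR303C) at -2.16 ± 0.45 (adjusted p = 0.0112), the peroxiredoxin gene AHP1 (YLR109W) at -1.95 ± 0.53 (adjusted p = 0.0317) and the glycolytic gene PGK1 (YCR012W) at -1.84 ± 0.48 (adjusted p = 0.028), followed by ICL2 at -1.73 ± 0.26 and GLO1 at -1.72 ± 0.31. Of 31 proteasome genes 0 rose and 2 fell (adjusted over the list alone, 0 and 14), with PRE10 at -1.32 ± 0.37. The proteasome list median was -0.66 (camera adjusted p = 1.4e-07, and adjusted p = 0.514 with an estimated correlation). In the heat shock list 0 rose and 3 fell (adjusted over the list alone, 0 and 3) among 16 genes, with HSP104 at -1.37 ± 0.36. The heat shock median was -0.46 (camera adjusted p = 0.00674, and adjusted p = 0.514 with an estimated correlation). No gene of the 18 for meiotic recombination passed, while their median was -0.73 (camera adjusted p = 0.000508, and adjusted p = 0.514 with an estimated correlation), and the 12 axis and synaptonemal complex genes likewise had a median of -0.79 with 0 called (camera adjusted p = 0.0171, and adjusted p = 0.738 with an estimated correlation). Of the lists camera called in this window, fry also called the GAL genes (adjusted p = 0.00347), division regulators (0.0373), ribosomal proteins (0.000803) and amino acid biosynthesis (0.00636). It did not call the spore wall (0.0592), heat shock (0.0592), prospore membrane (0.0613), proteasome (0.0704), recombination (0.137), ribosome biogenesis (0.326) or axis genes (0.39). Of the 383 rises, 115 belonged to the 445 genes outside the annotation table, whose median change was 1.84 against 0.02 for annotated genes, and 5 of the 8 largest rises were such genes, YPL205C at 6.02 ± 1.31 leading. Without the 40 min array 39 genes were called, without the -15, -10 or -5 min array 149, 174 and 257, without the 3 arrays of low spike-in slope 141, and without the 4 dim arrays 1354. The share of calls that were rises was 67.2%, 34.7% on the scanner software's processed signals and 46.2% of 301 among genes in the upper part by Cy5 signal. Cy5 carried RNA of the block, so here and in later windows this subset was chosen by the level in the arrested state. Its share of rises is therefore no independent check of direction.

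At 80 to 120 min 1589 genes changed (limma), 972 upwards and 617 downwards, with 880 rises and 330 falls of at least 2-fold. All 12 division regulators rose, with a median of 3.62 and 12 also adjusted over the list alone (camera adjusted p = 1.65e-08, and adjusted p = 0.503 with an estimated correlation). SPS1 led them at 6.43 ± 0.68 (adjusted p = 3.2e-05), followed by CLB1 (YGR108W) at 5.85 ± 0.90 (adjusted p = 0.00028), CDC5 at 4.61 ± 0.95 (adjusted p = 0.00212) and the cyclin gene CLB6 at 4.39 ± 1.06 (adjusted p = 0.00594). CLB6 stood at 5.86 at 80 min, 6.19 at 100 min and 1.12 at 120 min, and CDC5 at 5.91, 5.07 and 2.85. The largest rises of all were GAL7 at 9.34 ± 1.11 (adjusted p = 5.77e-05) and the sporulation genes SPR2 (YOR214C) at 8.75 ± 1.09 (adjusted p = 7.94e-05) and SPS4 (YOR313C) at 8.58 ± 1.01 (adjusted p = 5.77e-05). In the prospore membrane list 19 rose and 1 fell (adjusted over the list alone, 19 and 1) of 20, with SPO19 at 7.17 ± 1.22. The prospore membrane median was 4.26 (camera adjusted p = 1.95e-09, and adjusted p = 0.503 with an estimated correlation). In the spore wall list 15 rose and 1 fell (adjusted over the list alone, 15 and 1) of 20, with OSW2 at 5.98 ± 0.86 and SSP2 at 5.90 ± 0.83. The spore wall median was 4.32 (camera adjusted p = 2.87e-08, and adjusted p = 0.503 with an estimated correlation).

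At 80 to 120 min, of 13 subunits of the anaphase-promoting complex, the ubiquitin ligase that drives exit from metaphase, 10 rose and 0 fell (adjusted over the list alone, 11 and 1), with CDC26 at 5.12 ± 0.75 and APC11 at 3.53 ± 0.63. The anaphase-promoting complex median was 2.42 (camera adjusted p = 5.79e-05, and adjusted p = 0.503 with an estimated correlation). Of 21 spindle and kinetochore genes 9 rose and 1 fell (adjusted over the list alone, 10 and 1), with the spindle pole body gene SPC42 at 4.58 ± 0.71 and the midzone gene ASE1 at 3.80 ± 0.57. The spindle list median was 0.85 (camera adjusted p = 0.00696, and adjusted p = 0.589 with an estimated correlation). Among 14 genes listed as markers of mitotically cycling cells 6 rose and 0 fell (adjusted over the list alone, 8 and 0), with the cyclin gene CLN3 at 4.61 ± 0.81. CLN3 stood at 2.88 at 80 min, 3.86 at 100 min and 7.08 at 120 min, and without the 120 min array its change was 3.37. The mitotic-cycle list median was 1.29 (camera adjusted p = 0.00116, and adjusted p = 0.503 with an estimated correlation). Of 10 GAL genes 7 rose and 0 fell (adjusted over the list alone, 7 and 0). The GAL list median was 2.41 (camera adjusted p = 0.000134, and adjusted p = 0.503 with an estimated correlation).

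Also at 80 to 120 min, of 12 axis and synaptonemal complex genes 0 rose and 5 fell (adjusted over the list alone, 0 and 7), with the axis genes HOP1 (YIL072W) at -2.61 ± 0.49 (adjusted p = 0.00106) and RED1 (YLR263W) at -2.52 ± 0.40 (adjusted p = 0.000331). The chromosome axis median was -1.63 (camera adjusted p = 0.000105, and adjusted p = 0.514 with an estimated correlation). In the recombination list 0 rose and 6 fell (adjusted over the list alone, 0 and 6) of 18, with HOP2 at -1.99 ± 0.33 and the break-forming SPO11 at -1.86 ± 0.46. The recombination list median was -0.94 (camera adjusted p = 0.000164, and adjusted p = 0.514 with an estimated correlation). Of 31 proteasome genes 0 rose and 23 fell (adjusted over the list alone, 0 and 25), with PRE9 at -2.35 ± 0.37. The proteasome list median was -1.46 (camera adjusted p = 2.41e-12, and adjusted p = 0.503 with an estimated correlation). Of 14 acetate and glyoxylate metabolism genes 1 rose and 5 fell (adjusted over the list alone, 1 and 5). The acetate list median was -0.98 (camera adjusted p = 0.00354, and adjusted p = 0.514 with an estimated correlation), with the acetyl-CoA synthetase gene ACS1 at -2.15 ± 0.38. Ribosome biogenesis genes had a median of -0.66 with 1 of 39 risen and 0 fallen (camera adjusted p = 0.0181, and adjusted p = 0.921 with an estimated correlation), but 0.04 when arrays were centred on their medians. The fry adjusted p of this list was 0.483. The largest falls were the copper transporter gene CTR3 (YLR411W) at -3.14 ± 0.41 (adjusted p = 9.69e-05) and the flocculin gene FLO11 (YIR019C) at -2.84 ± 0.56 (adjusted p = 0.00141). Without the 80 min array 1041 genes were called and without the 100 min array 1058. Rises made up 61.2% of calls, 36.5% of 2755 on the processed signals and 44.9% of 1059 among genes of higher Cy5 signal.

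**Figure D2:**
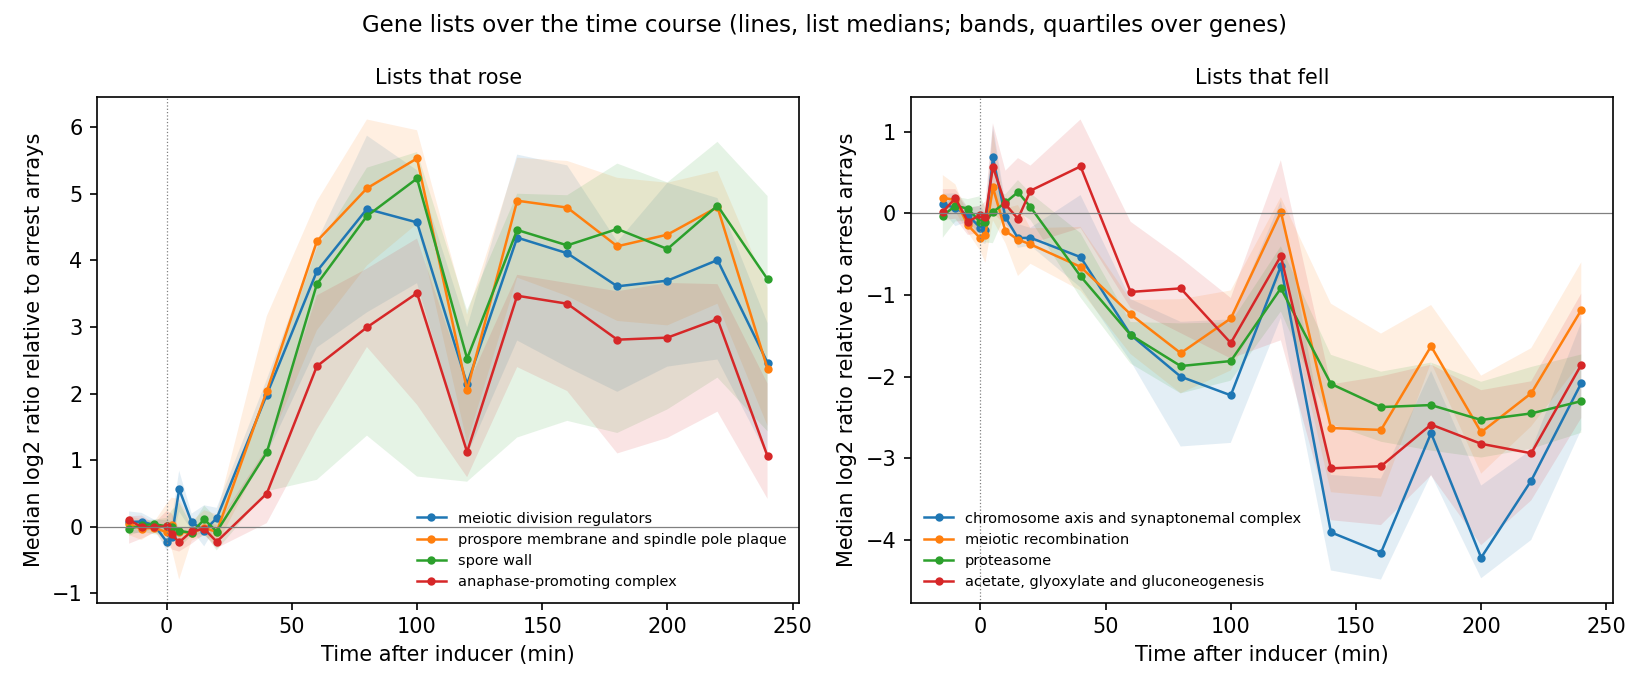
Median log2 ratio of 8 gene lists relative to the arrest arrays (y axis; bands, quartiles over genes) against minutes after the inducer (x axis), 1 array per time, with lists that rose on the left and lists that fell on the right. The division regulators had a median change of 3.62 at 80 to 120 min and the axis genes of -3.55 at 140 to 180 min, and the 120 min array lies closer to 0 than its neighbours for several lists.

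At 140 to 180 min 3048 genes changed (limma), 1572 upwards and 1476 downwards, with 1302 rises and 1120 falls of at least 2-fold. Rises were 51.6% of calls, 43.6% of 2832 on processed signals, 46.5% of 2660 after median centring and 35.5% of 1814 among genes of higher Cy5 signal. The largest rises included the hexose transporter gene HXT10 (YFL011W) at 10.10 ± 1.01 (adjusted p = 1.5e-06). The GATA-type factor gene GAT4 (YIR013C) was fitted at 10.01 ± 1.14 (adjusted p = 4.95e-06), but was well above background on only 1 of the 4 arrest arrays, so the size of its rise was not well measured. SRD1 (YCR018C) was not well above background on any arrest array and was at least 144-fold higher (adjusted p = 2.21e-06). That bound sets its mean Cy3 level at 140 to 180 min against the mean, over the arrest arrays, of the higher of its own signal and the lowest signal among probes well above background. The ubiquitin-conjugating enzyme gene UBC11 (YOR339C) rose by 7.86 ± 0.95 (adjusted p = 7.6e-06). All 12 division regulators were up, with a median of 4.10 and 12 also adjusted over the list alone (camera adjusted p = 7.3e-06, and adjusted p = 0.514 with an estimated correlation), SPS1 at 7.45 ± 0.68 (adjusted p = 7.06e-07) and the APC activator gene CDC20 at 4.93 ± 0.96 (adjusted p = 0.000485) among them. In the prospore membrane list 19 rose and 1 fell (adjusted over the list alone, 19 and 1) of 20, with SMA2 at 7.96 ± 1.54. The prospore membrane median was 4.80 (camera adjusted p = 6.97e-07, and adjusted p = 0.514 with an estimated correlation). In the spore wall list 15 rose and 1 fell (adjusted over the list alone, 16 and 2) of 20, with SSP2 at 6.92 ± 0.83. The spore wall median was 4.42 (camera adjusted p = 9.95e-06, and adjusted p = 0.503 with an estimated correlation).

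At 140 to 180 min, of 13 subunits of the anaphase-promoting complex 10 rose and 2 fell (adjusted over the list alone, 10 and 2), with CDC27 at 4.38 ± 0.55. The anaphase-promoting complex median was 3.38 (camera adjusted p = 0.00315, and adjusted p = 0.514 with an estimated correlation). Of 21 spindle and kinetochore genes 12 rose and 2 fell (adjusted over the list alone, 13 and 2). The spindle list median was 1.03 (camera adjusted p = 0.00831, and adjusted p = 0.591 with an estimated correlation). In the mitotic-cycle list 10 rose and 0 fell (adjusted over the list alone, 10 and 0) of 14, with EGT2, a gene of cell separation, at 4.28 ± 0.70. The mitotic-cycle list median was 1.92 (camera adjusted p = 0.00143, and adjusted p = 0.503 with an estimated correlation). Of 18 mating-type and haploid genes 11 rose and 2 fell (adjusted over the list alone, 13 and 2), with the G-protein subunit genes STE18 at 5.48 ± 0.93 and STE4 at 2.82 ± 0.76. The mating-type list median was 1.19 (camera adjusted p = 0.00711, and adjusted p = 0.514 with an estimated correlation). Of 10 GAL genes 6 rose and 0 fell (adjusted over the list alone, 8 and 0). The GAL list median was 2.38 (camera adjusted p = 0.007, and adjusted p = 0.518 with an estimated correlation).

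Also at 140 to 180 min, of 12 axis and synaptonemal complex genes 0 rose and 11 fell (adjusted over the list alone, 0 and 11), with SPO22 (YIL073C), which acts in crossover formation, at -4.75 ± 0.49 (adjusted p = 1.76e-06). The chromosome axis median was -3.55 (camera adjusted p = 1.32e-06, and adjusted p = 0.514 with an estimated correlation). In the recombination list 0 rose and 15 fell (adjusted over the list alone, 0 and 16) of 18, with the meiotic recombinase gene DMC1 (YER179W) at -4.70 ± 0.78 (adjusted p = 0.000128). The recombination list median was -2.19 (camera adjusted p = 9.09e-06, and adjusted p = 0.514 with an estimated correlation). The master regulator of meiotic entry IME1 (YJR094C) fell, at -2.00 ± 0.63 (adjusted p = 0.0137), in an early-regulator list where 2 rose and 6 fell (adjusted over the list alone, 2 and 6) of 10 (camera adjusted p = 0.146). All 14 acetate and glyoxylate genes fell, with the malate synthase gene MLS1 (YNL117W) at -4.83 ± 0.42 (adjusted p = 6.25e-07) and a median of -2.91, and 14 fell adjusted over the list alone (camera adjusted p = 1.58e-07, and adjusted p = 0.503 with an estimated correlation). Of 34 oxidative phosphorylation genes 0 rose and 22 fell (adjusted over the list alone, 0 and 22), with ATP2 at -3.56 ± 0.35. The oxidative phosphorylation median was -1.28 (camera adjusted p = 2.96e-06, and adjusted p = 0.544 with an estimated correlation). Of 31 proteasome genes 0 rose and 28 fell (adjusted over the list alone, 0 and 28). The proteasome list median was -2.21 (camera adjusted p = 2.41e-12, and adjusted p = 0.503 with an estimated correlation). In the heat shock list 4 rose and 9 fell (adjusted over the list alone, 4 and 9) of 16, with HSP82 at -3.94 ± 0.30 and the catalase gene CTT1 at 3.85 ± 0.89. The heat shock median was -1.45 (camera adjusted p = 0.0158, and adjusted p = 0.514 with an estimated correlation), where median centring gave a camera adjusted p of 0.0922. The largest single falls were CTR3 at -5.89 ± 0.41 (adjusted p = 1.4e-07), FLO11 at -5.74 ± 0.56 (adjusted p = 1.22e-06) and the fatty acid desaturase gene OLE1 (YGL055W) at -5.71 ± 0.61 (adjusted p = 2.4e-06).

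At 200 to 240 min 2525 genes differed from arrest (limma), 1241 upwards and 1284 downwards, with 1042 rises and 933 falls of at least 2-fold. Rises were 49.1% of calls, 41.7% of 2586 on processed signals, 43.4% of 2251 after median centring and 35.9% of 1629 among genes of higher Cy5 signal. HXT10 stood at 11.15 ± 1.01 (adjusted p = 6.26e-07) and SPS4 at 9.19 ± 1.01 (adjusted p = 2.99e-06). The same limit holds for GAT4, fitted at 10.94 ± 1.14 (adjusted p = 1.9e-06). The sporulation glucoamylase gene SGA1 (YIL099W) reached 7.92 ± 0.73 (adjusted p = 7.25e-07) and the chitinase-like gene CTS2 (YDR371W) 7.91 ± 0.81 (adjusted p = 1.58e-06). In the spore wall list 16 rose and 1 fell (adjusted over the list alone, 17 and 2) of 20, with SSP2 at 6.96 ± 0.83. The spore wall median was 4.43 (camera adjusted p = 2.68e-07, and adjusted p = 0.503 with an estimated correlation). In the prospore membrane list 18 rose and 1 fell (adjusted over the list alone, 18 and 1) of 20. The prospore membrane median was 4.03 (camera adjusted p = 2.6e-06, and adjusted p = 0.514 with an estimated correlation). Of 12 division regulators 9 rose and 0 fell (adjusted over the list alone, 11 and 0). The division regulator median was 3.53 (camera adjusted p = 1.76e-05, and adjusted p = 0.514 with an estimated correlation), while the securin gene PDS1 stood at 0.67 ± 0.36 (adjusted p = 0.146) and SPO12 at 2.16 ± 0.93 (adjusted p = 0.0709). Of 13 subunits of the anaphase-promoting complex 9 rose and 2 fell (adjusted over the list alone, 10 and 2). The anaphase-promoting complex median was 2.44 (camera adjusted p = 0.00932, and adjusted p = 0.578 with an estimated correlation). In the mitotic-cycle list 6 rose and 0 fell (adjusted over the list alone, 7 and 0) of 14. The mitotic-cycle list median was 1.54 (camera adjusted p = 0.0112, and adjusted p = 0.514 with an estimated correlation). In the GAL list 5 rose and 0 fell (adjusted over the list alone, 6 and 0) of 10. The GAL list median was 2.01 (camera adjusted p = 0.00808, and adjusted p = 0.528 with an estimated correlation).

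At 200 to 240 min, in the axis and synaptonemal complex list 0 rose and 11 fell (adjusted over the list alone, 0 and 11) of 12. The chromosome axis median was -3.02 (camera adjusted p = 1.56e-06, and adjusted p = 0.514 with an estimated correlation). In the recombination list 0 rose and 13 fell (adjusted over the list alone, 0 and 16) of 18. The recombination list median was -2.06 (camera adjusted p = 5.86e-06, and adjusted p = 0.503 with an estimated correlation). All 14 acetate and glyoxylate genes were below arrest, also adjusted over the list alone (14), with ACS1 at -4.47 ± 0.38 (adjusted p = 3.31e-07). The acetate list median was -2.49 (camera adjusted p = 2.78e-07, and adjusted p = 0.503 with an estimated correlation). Of 31 proteasome genes 0 rose and 28 fell (adjusted over the list alone, 0 and 28). The proteasome list median was -2.46 (camera adjusted p = 3.48e-14, and adjusted p = 0.503 with an estimated correlation). In oxidative phosphorylation 0 rose and 16 fell (adjusted over the list alone, 0 and 16) of 34. The oxidative phosphorylation median was -0.98 (camera adjusted p = 5.54e-05, and adjusted p = 0.609 with an estimated correlation). The meiotic kinase gene IME2 (YJL106W) fell, at -1.30 ± 0.38 (adjusted p = 0.0117), and SUM1 (YDR310C), which encodes the repressor of middle sporulation genes, rose by 0.78 ± 0.28 (adjusted p = 0.0321). CTR3 at -6.02 ± 0.41 (adjusted p = 6.58e-08) and the co-chaperone gene SGT2 (YOR007C) at -4.35 ± 0.33 (adjusted p = 2.11e-07) were among the largest falls. Over all windows, 52 list calls were made with camera's preset correlation of 0.01 and 0 with an estimated correlation, and the median, the mean and the direction of the test had the same sign in each of the 52. Arrest arrays share slide 1 with no other window, so slide and time cannot be told apart in any comparison against arrest. With slide as a random block, at a fitted correlation within slides of 0.012, the counts against arrest were 0, 456, 1523, 3017 and 2467 in time order. Such a block does not remove an offset of slide 1.

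From 20 to 60 min to 80 to 120 min, 401 genes changed (limma), 218 upwards and 183 downwards. Rises were led by GAT4 at 6.27 ± 1.22 (adjusted p = 0.0148), YDR042C at 4.46 ± 1.02 (adjusted p = 0.0225), the cell wall gene PIR5 at 4.30 ± 1.07 (adjusted p = 0.0301) and SPR2 at 4.26 ± 1.17 (adjusted p = 0.0395). GAT4 and PIR5 were well above background on 2 of the 3 earlier arrays. The largest falls were YBR238C at -4.25 ± 1.01 (adjusted p = 0.0264), YPR142C at -4.20 ± 1.06 (adjusted p = 0.0322) and YLR198C at -4.19 ± 0.74 (adjusted p = 0.00924), the last 2 well above background on 2 of the 3 later arrays. The division regulators differed by a median of 1.79 between these windows, and by 2.54 with slide as a fixed block and within slide 3. Slide 3 holds 1 later array (80 min), so the count of genes passing within it is not given. With slide as a fixed block 0 genes passed (708 at an unadjusted p under 0.05), and with only the arrays of both windows in the fit 0 passed (919 unadjusted). Without the 20, 40, 60, 80, 100 or 120 min array the count was 25, 17, 1103, 196, 30 and 827, and rises were 54.4% of calls against 43.9% of 1031 on processed signals and 26.7% of 86 after median centring.

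From 80 to 120 min to 140 to 180 min, 1233 genes changed (limma), 517 upwards and 716 downwards, while the median over all genes shifted by -0.12. The largest rises were the end-joining gene NEJ1 at 4.03 ± 1.18 (adjusted p = 0.0262), GID10 at 4.01 ± 0.59 (adjusted p = 0.000614), the disulfide isomerase family gene MPD1 at 3.91 ± 0.53 (adjusted p = 0.000487), YLR012C at 3.70 ± 0.62 (adjusted p = 0.00133) and SRD1 at 3.56 ± 0.95 (adjusted p = 0.0177), of which GID10, MPD1 and YLR012C were well above background on 2 of the 3 earlier arrays. The largest falls were YDL187C at -5.60 ± 1.40 (adjusted p = 0.0124), YML034C-A at -5.24 ± 1.58 (adjusted p = 0.0295) and YPL205C at -4.87 ± 1.40 (adjusted p = 0.0246), all outside the annotation table. Acetate and glyoxylate genes differed by a median of -2.07 and the axis genes by -1.80, and by -2.64 and -2.40 within slide 4 and with slide as a fixed block. Within slide 4 (140 and 160 min against 100 and 120 min) 1540 genes passed, with slide as a fixed block 3 (2096 unadjusted), and with only the arrays of both windows 0 (1689 unadjusted). On slide 4 the median Cy3 signal was 2386.5 and 1618 against 199 and 60.5, so time and Cy3 signal cannot be told apart there. With Cy3 signal as a covariate over all arrays 704 genes passed. Without the 80, 120, 140 or 160 min array the count was 787, 735, 610 and 355, and rises were 41.9% of calls against 61.3% of 992 on processed signals and 63.5% of 458 after median centring.

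Between 140 to 180 min and 200 to 240 min 4 genes rose and 0 fell (limma, 554 at an unadjusted p under 0.05). They were the dityrosine synthesis gene DIT1 (YDR403W) at 4.17 ± 0.43 (adjusted p = 0.000145), YBR116C at 3.77 ± 0.54 (adjusted p = 0.00464), the transketolase gene TKL2 (YBR117C) at 3.21 ± 0.45 (adjusted p = 0.00464) and the translation regulator gene CAF20 (YOR276W) at 2.11 ± 0.34 (adjusted p = 0.0165). DIT1 stood at 1.03 at 180 min, 4.13 at 200 min, 5.00 at 220 min and 6.28 at 240 min relative to arrest. Spore wall genes as a list differed by a median of -0.22, and by -0.40 within slide 5 and with slide as a fixed block. Slide 5 holds 1 earlier array (180 min), so the count of genes passing within it is not given. With slide as a fixed block 0 genes passed (62 unadjusted) and with only the arrays of both windows 0 (465 unadjusted). Without the 140, 160, 180 or 200 min array the count was 1, 1, 145 and 13, and with only annotated genes it was 3.

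Over the whole course 4513 of 6136 genes (73.5%) changed along a spline of time (limma moderated F). For genes called by this test that rose at least 1 log2 above arrest, the time of passing the midpoint between arrest and peak was 16.6 min for NDT80, 4.19 min for the uracil permease gene FUR4, 6.36 min for MTH1, 9.46 min for GAL3, 15.3 min for GAL2, 29.2 min for GAL7, 35.6 min for GAL1, 37.1 min for GAL80, 39.3 min for GAL10 (well above background on 1 of the 4 arrest arrays) and 49.5 min for GCY1. It was 30.1 min for CDC5, 41.0 min for CLB1, 53.0 min for SPS1 and 192 min for DIT1. Median midpoint times over rising list members were 9.86 min for 34 ribosome biogenesis genes, 12.5 min for 92 ribosomal protein genes, 29.2 min for 9 GAL genes, 43.9 min for 19 prospore membrane genes, 46.7 min for 12 division regulators, 49.6 min for 18 spore wall genes and 53.9 min for 11 anaphase-promoting complex genes. Across all 2235 rising genes the median was 43.6 min, with quartiles of 4.83 and 71.2 min, although no single gene passed at 2 to 15 min. A time between 2 and 10 min, as for FUR4, MTH1 and GAL3, rests in part on the 5 min array, whose spike-in slope was 0.446. No test was applied to these times, each was read between single arrays, and genes are not replicates.

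Before release, over -15 to 0 min, 1080 genes (17.6%) had a slope (limma), 681 upwards and 399 downwards, with 2125 at an unadjusted p under 0.05. Cytosolic ribosomal proteins held 41 upward and 0 downward slopes among 137 genes, with a median of 0.41 log2 per 10 min, and the recombination list 0 upward and 5 downward among 18, with a median of -0.41. The Cy3 signal fell over the same arrays, from 3392 and 3146 to 1092 and 821. Without the 0 min array 0 genes passed.

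**Figure D3:**
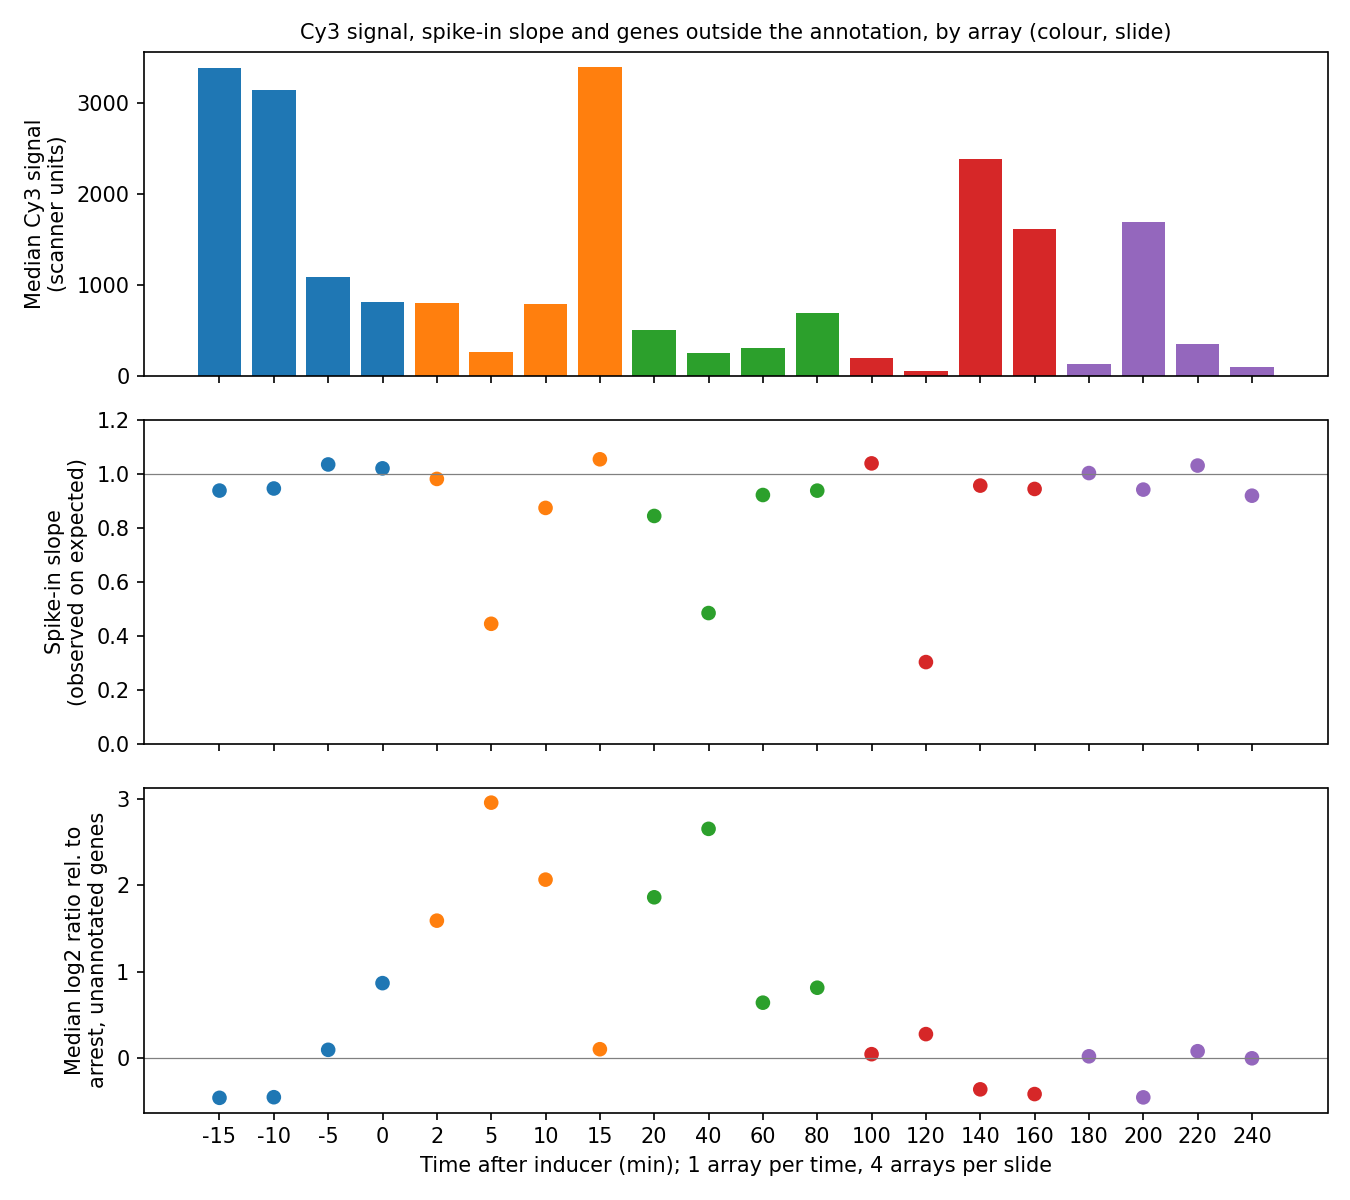
Median Cy3 signal in scanner units (top), slope of observed on expected spike-in log ratios (middle) and median log2 ratio relative to arrest of the 445 genes outside the annotation table (bottom) for the 20 arrays in time order (x axis, minutes after the inducer), coloured by slide. The spike-in slope was 0.446 at 5 min, 0.485 at 40 min and 0.304 at 120 min and between 0.844 and 1.05 on the other 17 arrays.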

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

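The test of the 120 min array, the value centred within slides and the series of genes outside the annotation were chosen only after the results were seen. Dixon's test was applied to 64 values, of which 5 lay far from the others of their group, where chance gives about 1 in 20. At 0 min the division regulators had a median of -0.22 and IME2 stood at -0.25, relative to the arrest mean. The anaphase-promoting complex had a median of 0.10 at -15 min. At 5 min the recombination list had a median of 0.32 and observed and expected spike-in ratios correlated at 0.483.

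Spike-in controls, which no comparison uses, gave slopes of observed on expected log ratios of 0.446 at 5 min, 0.485 at 40 min and 0.304 at 120 min, against 0.844 to 1.05 on the other 17 arrays. These 3 arrays lay at position 2 of their slide, but so did those at -10 min and 200 min, with slopes of 0.946 and 0.942. Reference RNA in the Cy3 channel would shrink all ratios. Genes at least 1 log2 from arrest had slopes on the mean of their neighbours of 1.45 at 5 min and 1.24 at 40 min. Over annotated genes alone the slopes were 1.34 and 1.08. They show no shrinkage, but levels that step between neighbouring arrays move such a slope too, so this cause could not be excluded there. At 120 min the slope was 0.42, and the bound written for it (excluded at or above the lowest value of the other arrays, 0.204) would have excluded this cause. That bound was set aside after the result was seen, because its lowest array, 15 min, had a spike-in slope near 1 and so a low gene slope does not separate the cases. Reference RNA stays open for all 3 arrays, with no biological explanation tested.

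Genes outside the annotation table made up 115 of the 383 rises at 20 to 60 min, and the median change of all 445 was 1.84 against 0.02 for annotated genes. A low level in the Cy5 reference is argued against for these arrays, since within equal Cy5 signal the medians differed by 1.51 (95% interval 1.29 to 1.74). That interval comes from resampling genes, which are not replicates, and holds no spread between arrays. Additive Cy3 background on dim arrays could not be decided. The median ratio of the 115 rising genes alone was set against the Cy3 signal over 13 arrays after release, outside 20 to 60 min. Spearman rho was -0.313 (permutation p = 0.298) and Pearson r -0.25 (permutation p = 0.413), both 0.413 after Benjamini-Hochberg adjustment over the pair. Without the 2 arrays farthest from the median r was -0.38, and centred within slides it was -0.85. Release was not tested as an explanation, but the median of all 445 genes already went from -0.46 at -15 min to 0.87 at 0 min, before the inducer, and was 2.96 at 5 min and 0.10 at 15 min, which argues against release as the whole cause.

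The slopes before release were called for 1080 genes while the Cy3 signal fell over the same 4 arrays. Falling Cy3 signal is a candidate explanation, since across the called genes, which are not independent replicates, the slope correlated with the response to Cy3 signal within slides after release at r = -0.63 (-0.43 over all genes). Drift of the arrested culture is another, since the slope correlated with the change at 2 to 15 min at r = 0.84 (0.74 over all genes). Both tests came out as their explanation needs, and the arrays at 2 to 15 min differ in Cy3 signal too, so the explanations were not separated. Ribosomal protein genes, with 41 upward slopes, belong to this pattern.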

How the results depend on the processing

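The settings with a Cy3 covariate, without the 4 dim arrays, without the 120 min array, without the 3 low spike-in arrays, with an offset of 10, with annotated genes alone and with the upper part by Cy5 signal were chosen only after the data were seen. Of 392 named gene calls 280 were kept under every setting that was run for them and 112 were lost under at least 1, with 0 reversed. The strict filter was run for 323 of them, annotated genes for 373, the upper part by Cy5 signal for 220, the fixed block for 24 and each array left out for the calls it enters, and sign changes of values never called were not counted. Processed signals gave 2755 genes at 80 to 120 min and 1031 for 80 to 120 against 20 to 60 min. Median centring gave 306 at 20 to 60 min, 86 and 458 for the consecutive pairs up to 140 to 180 min, and 1888 slopes before release. The strict filter gave 2798 genes over time, 646 slopes and an autophagy midpoint of 46.7 min against 101 min. With only the arrays of both windows the 3 consecutive counts were 0, 0 and 0 (limma, unadjusted 919, 1689 and 465), and with slide as a fixed block 0, 3 and 0 (unadjusted 708, 2096 and 62). Both settings leave fewer arrays in the fit. An estimated correlation called 0 lists against 52. The Cy3 covariate gave 958 and 704 genes for the consecutive pairs up to 140 to 180 min. Without the 4 dim arrays 1354 genes changed at 20 to 60 min and 30 between the last windows, and without the 120 min array 827 and 735 for the earlier pairs. Without the 3 low spike-in arrays 141 changed at 20 to 60 min. An offset of 10 gave 804 for 80 to 120 against 20 to 60 min, and 2166 at 80 to 120 min against arrest, where the offset of 50 gave 1589. Genes in the upper part by Cy5 signal gave 301, 1059, 1814 and 1629 against arrest, 1 between the last windows, 2404 over time and 351 slopes, with fewer genes tested. Leaving out each array in turn gave 0 to 304 genes at 2 to 15 min, 39 to 787 at 20 to 60, 1041 to 1929 at 80 to 120, 2321 to 3178 at 140 to 180 and 1868 to 2720 at 200 to 240 min. It gave 17 to 1103, 355 to 1745 and 1 to 145 for the consecutive pairs, 4053 to 4939 over time, 0 to 1372 slopes and 48 to 56 lists. Without the 40 min array 49 of the 59 named calls that use the 20 to 60 min window, against arrest or against 80 to 120 min, were lost, and the slope count was 0 without the 0 min array. Except where fewer genes or arrays enter, the cause was not tested. The median change of all genes against arrest was -0.12, -0.24, -0.36, -0.19 and -0.13 with processed signals, where loess gave 0.028, 0.057, 0.019, -0.032 and -0.013. With median centring it was 0.11 at 20 to 60 min, and from 80 to 120 to 140 to 180 min -0.22 where loess gave -0.12. In that pair 50 called genes had the opposite sign after median centring and 405 were shared. Quantile scaling of intensities leaves ratios as they are and tested nothing. Slide as a block was not run for gene lists, which camera does not take, nor for the slope, whose arrays share a slide, and robust moderation was not run for camera. No paired analysis was possible because the replicate numbers follow time and pair no samples. Signal over background limits the 120 min array most, at 68.9% of Cy3 spots.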

Other observations

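All tests in this part were written before their results were seen, and the lists described here were chosen for mention afterwards. The ribosome biogenesis list stood highest at 20 min. Its median relative to arrest was 0.77 at 10 min, 1.68 at 15 min and 1.90 at 20 min, then 0.37 at 40 min and -0.45 at 60 min. Cytosolic ribosomal proteins stood at 0.83 at 15 min, 1.27 at 20 min, 1.17 at 40 min, 0.99 at 60 min and 0.35 at 80 min. These are 1 array per time, the 20 min array is among the 4 dim ones, and the difference between both lists was not tested.

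Histone genes had a median of -0.48 (camera adjusted p = 0.562) at 140 to 180 min, where 2 rose and 3 fell (adjusted over the list alone, 2 and 3) of 10. Of 15 glycogen and trehalose genes 6 rose and 4 fell (adjusted over the list alone, 6 and 5) at 200 to 240 min, with a median of 0.45 (camera adjusted p = 0.713). Of 10 drug efflux genes 3 rose and 1 fell (adjusted over the list alone, 3 and 1) at 80 to 120 min, with a median of 0.48 (camera adjusted p = 0.791). Among early meiotic regulators 1 rose and 6 fell (adjusted over the list alone, 1 and 7) of 10 at 200 to 240 min, with a median of -1.37 (camera adjusted p = 0.0564).

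Other splits of the same arrays into groups of the same sizes were counted for each result. For genes changed against arrest, 1 of 35 splits, the real one, gave as many at 20 to 60 min (570, highest other 0), 80 to 120 min (1589, highest other 284), 140 to 180 min (3048, highest other 1389) and 200 to 240 min (2525, highest other 1142). Other groupings of these arrays thus did not reach the real counts. The splits cannot tell release from slide or drift, because the times are consecutive and slide 1 holds the arrest arrays alone. At 2 to 15 min the real count was 0, so all 35 splits had to give as many and the count tests nothing (highest other 372, with the -15, -10, -5 and 15 min arrays together). Over time, 1 of 100 orders, the real one, gave as many (4513, highest other 238). Slides follow time, so the orders cannot tell release from slide or drift either. For the number of lists called, chance was not excluded, with 22, 22, 14, 8 and 16 of 35 splits giving as many in time order (real 4, 11, 12, 14 and 11, highest other 12, 15, 14, 15 and 14). The consecutive pairs have 10 splits, too few for a share under 0.05, and gave as many in 2, 1 and 2 of them. Their real counts were 401, 1233 and 4. The highest others were 1234 (20, 40 and 120 min together), 8, and 588 (140, 160 and 200 min together). Counts several times the real ones point to a structure of the samples. In the last pair the median Cy3 signal was 2386.5, 1618 and 1696 at 140, 160 and 200 min. It was 129.5, 357.5 and 97 at 180, 220 and 240 min, so that split also divides arrays of high and low Cy3 signal. Cy3 signal was not tested as its cause.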
